A study of Mus musculus with 26 samples.

How the data were processed

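RNA was sequenced from intestinal organoids of C57BL/6J mice, which are epithelial cultures grown in a gel matrix from intestinal tissue. There were 3 organoid types: small intestine (SI), Paneth cell-skewed (PC) and colon. Per the labels' protocols, all were grown with epidermal growth factor, Noggin and R-spondin, and PC organoids were also given the GSK3 inhibitor CHIR99021 and valproic acid, a histone deacetylase inhibitor. Organoids were left unstimulated or were given 100 ng/mL of purified flagellin for 4 hours. SI had 3 libraries in each condition, PC 6 and colon 4, so 26 libraries fell into 6 groups. The series' design text calls the replicates separate experimental replicates, and the labels number them within each group. Per the labels' protocols, ribosomal RNA was depleted, libraries were made with a TruSeq kit, and single-end reads were sequenced on a HiSeq instrument. Whether the kit kept the strand of the RNA is not given in the sources used here.

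Each library's table listed 103215 transcripts with their length, effective length and estimated count, per the file headers. The submitters' processing notes name CASAVA, bcl2fastq 2.17, kallisto 0.43.0 and the genome build GRCm38. The authors' estimated counts were reads assigned to transcripts, not scaled between libraries, per the file headers and the values. For transcripts over 1000 bases the deposited effective length was 50 bases under the length in SI and PC libraries and 349 bases under it in colon libraries. In the colon tables, transcripts shorter than that difference rarely held a count. The transcript tables held no entry for Malat1, Neat1, Rn7sk, Rmrp or Rpph1.

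Of the listed transcripts, 101559 (98.4%) were matched by identifier to 32945 genes of the GENCODE vM21 annotation of GRCm38. Unmatched transcripts held 0.53% to 1.01% of a library's estimated counts and were left out. Estimated counts were summed per gene and rounded to whole numbers. CPM values are counts-per-million values scaled with edgeR's TMM factors. Transcripts-per-million values (TPM) were computed here from the deposited estimated counts and effective lengths, since the tables list none. The plan had assumed that they did.

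Total estimated counts ranged from 18404218 to 57034878 per library. The median standard error of a gene's log2 fold change was 0.147 in SI, 0.138 in PC and 0.133 in colon organoids. Fold changes against a group without counts were given as lower bounds computed with 3 counts over the group. Where a group held 1 to 3 counts, the ratio of CPM was given with an exact 95% interval for a ratio of counts. Intervals and bounds cover counting error only.

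Each of 8 comparisons was fitted with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test), with Benjamini-Hochberg adjustment and a threshold of 0.05. They were the flagellin response within each type, the difference of responses between each pair of types, and unstimulated PC or colon organoids against unstimulated SI organoids. Each response was fitted on its own type's libraries. Each difference of responses was fitted on the libraries of both types, and each baseline comparison on the unstimulated libraries alone. The standard error of a log2 fold change was its size divided by the square root of the F statistic. SI libraries enter both PC and colon comparisons with SI, so no overlap was computed between those. Overlaps of calls between the responses of different types, which share no library, were tested with a one-sided Fisher's exact test.

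There were 21 gene lists, which were tested with limma 3.58.1: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. Adjusted p-values of lists were computed over the lists of a comparison. The list called flagellin sensors, or sensors, held Tlr5, Naip1, Naip2, Naip5, Naip6 and Nlrc4. It also held the inflammasome genes Casp1, Casp4, Gsdmd, Pycard and Il18. The list's name is a label and does not mean that each member binds flagellin. The comparisons, the lists, the rule for named genes and all alternatives other than those called added were fixed before the data were examined. The rule named Tlr5, the 10 largest rises and 5 largest falls of a response, and up to 4 members per list with the smallest adjusted p. A named rise or fall needed a mean of at least 1 CPM and every stimulated library on the same side of the unstimulated mean. For differences and baseline comparisons it named the 5 largest changes in each direction, or, where fewer than 10 genes passed, all of them and the 10 with the smallest p. Predicted and clone-named genes and pseudogenes were counted but not named. A list member that did not pass was chosen as the most abundant one. Genes named outside the rule are said to be so.

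Same-numbered colon libraries deviated together from their group means. The correlations of their deviations across genes were 0.313, 0.263, 0.419 and 0.322, all above the limit of 0.1 set for pairing, so the colon numbers were read as pairs from the data, not from the labels. A fit with the number as a block was an alternative for all comparisons. Libraries were also classed by Y-linked transcripts (Ddx3y at 10 CPM or more), which were present in all 6 SI libraries, absent from all 8 colon libraries and split among PC libraries. They were present in PC unstimulated 5 and 6 and PC flagellin 1, 5 and 6, and absent from the other 7. PC number 1 thus joins an unstimulated library without them to a stimulated library with them, so blocked fits of PC rest on an unlike pair. The class was treated as a batch in PC. The sex of the animals is not given in the sources used here, so whether the class marks their sex, another batch or both was not settled, and values within a class hold for either reading. No pair of libraries in a group was a copy, since the lowest chi-square per degree of freedom between any pair was 12.6.

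Alternatives were DESeq2's size factors in the edgeR fit, no expression filter, DESeq2 1.42.0, limma on log2(TPM + 1), a replicate block, an offset for effective length, leaving out each library, and, for responses, all 26 libraries in 1 fit. Alternatives added after seeing the data were the Y-linked class as a covariate, fits within a class, fits without pseudogenes and genes under 400 bases, and fits on 3 against 3 libraries. Counts, medians and camera tests of list members of at least 1000 bases were added too. Against SI, limma on TPM moved the median log2 fold change of all genes from 0.04 to -0.22 for PC and from -0.01 to -0.22 for colon. Leaving out the filter moved it to 0.13 for PC. All scripts ran in Python 3.11.15, with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3.

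The scripts were tested on simulated data with 200 changed genes per comparison, 50 at each size. Changed genes were drawn from those with a mean of at least 50 counts, so the shares below do not cover rarer genes. Adjustment is stricter where fewer genes change, so they do not carry over to responses with few or no calls. In the SI design, 42% of genes changed 1.5-fold, 84% of those changed 2-fold and 100% of those changed 4-fold were called, with 25 false calls among 14919 unchanged genes. In the PC design these shares were 62%, 84% and 98%, with 7 false calls among 15776, and in the colon design 50%, 96% and 98%, with 12 among 14970. For the difference of responses between PC and SI organoids, 60% of 2-fold and 78% of 4-fold changes were called. For colon and SI these were 50% and 88%, and for colon and PC 54% and 78%. For the baseline comparisons, 84% of 2-fold changes were called between PC and SI and 92% between colon and SI. A list changed on purpose was called in every design, and none of the 20 others was. Genes were simulated independently of each other, and every member of the changed list was raised. The simulation therefore does not test the preset correlation on lists whose genes vary together.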

Results

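Gene expression was measured in SI, PC and colon organoids without stimulation and after 4 hours with 100 ng/mL flagellin. Flagellin is a bacterial protein that Tlr5 senses at the cell surface and that some Naip proteins, acting with Nlrc4, sense in the cytosol. There were 3 SI, 6 PC and 4 colon libraries in each condition. Unstimulated libraries held 20198531 to 27876031 (SI), 18404218 to 57034878 (PC) and 20564470 to 26573391 (colon) estimated counts. Stimulated libraries held 29931052 to 32323981, 26642190 to 49822409 and 23055309 to 27403441. Values after ± are standard errors of log2 fold changes, or standard deviations (SD) of CPM. Unless another tool is named, adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Those of lists come from camera.

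**Figure D1:**
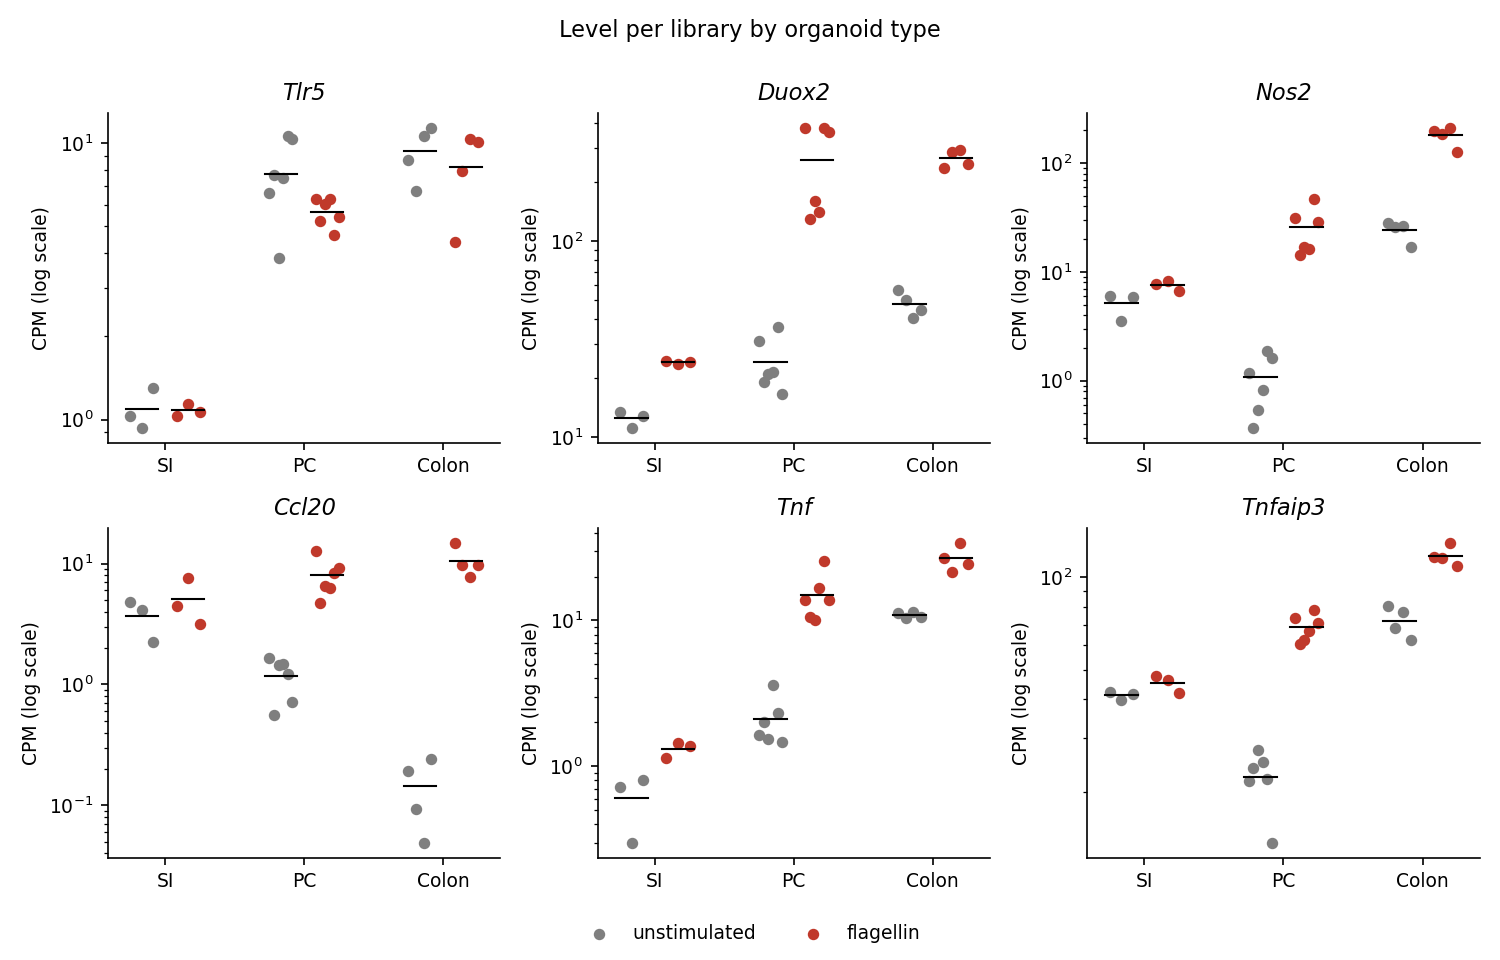
CPM (log axis) of Tlr5, Duox2, Nos2, Ccl20, Tnf and Tnfaip3 in each of the 26 libraries by organoid type, with unstimulated libraries in grey, flagellin libraries in red and the group mean as a black bar. Mean Duox2 moved from 12.5 to 24.1 CPM in SI, from 24.3 to 259 CPM in PC and from 48.0 to 266 CPM in colon organoids.

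Flagellin's effect was first read in SI organoids. Duox2, the dual oxidase that releases hydrogen peroxide at the epithelial surface, went from 12.5 ± 1.2 CPM (SD, n = 3) to 24.1 ± 0.44 CPM, a log2 fold change of 0.94 ± 0.12 with an unadjusted p of 1.4e-05 and an edgeR adjusted p of 0.11. Its partner Duoxa2 had a log2 fold change of 0.93 ± 0.33, the inducible nitric oxide synthase Nos2 0.53 ± 0.24, Tnf 1.11 ± 0.50 and the chemokine Ccl20 0.45 ± 0.37, none past the threshold. Birc3, Tnfaip3 and Tlr5 had values of -0.12 ± 0.13, 0.12 ± 0.09 and -0.03 ± 0.42. No gene of 15470 passed in edgeR's quasi-likelihood test, with 408 at an unadjusted p under 0.05. DESeq2 called 10, 4 higher and 6 lower, among them Duox2, Rps23, Serpind1 and Ceacam2. Limma on TPM called 0, the fit without a filter 5 and the fit with a replicate block 1. Leaving out SI unstimulated 1 or flagellin 1 gave 2 calls each, and leaving out unstimulated 3 or flagellin 2 gave 1 each.

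Among the lists, members of antimicrobial and mucosal defence, chemokines and the mitochondrial transcripts of the RNA quality list lay higher in stimulated SI organoids by camera's preset correlation. No member passed over all genes. Of 18 defence genes, 15 had positive values with a median of 0.18, and 1, Duox2, was higher when adjusted over the list alone (camera adjusted p = 9.9e-05, adjusted p = 0.35 with an estimated correlation). The 6 chemokines had a median of 0.24, none past the test over the list alone (camera adjusted p = 0.024, adjusted p = 0.65 with an estimated correlation). The 7 mitochondrial transcripts had a median of 0.34, with 5 higher when adjusted over the list alone (camera adjusted p = 1.0e-06, adjusted p = 0.48 with an estimated correlation). Every stimulated SI library held more counts in total than every unstimulated one, so depth and stimulation cannot be told apart here. In the other 18 lists no member passed over all genes or over the list alone, and the lowest camera adjusted p was 0.33. These were flagellin sensors, Toll-like receptors, NF-kB regulators, cytokines, interferon-stimulated genes, immediate early genes, endoplasmic reticulum stress, cell cycle, and markers of Paneth, stem, goblet, enteroendocrine, tuft, enterocyte, colonocyte, haematopoietic and stromal cells and Wnt targets. Median and mean differed in sign for sensors (-0.03 and 0.01), Toll-like receptors (0.06 and -0.00), colonocyte (0.04 and -0.02), stromal (-0.02 and 0.04) and enterocyte markers (-0.00 and 0.01), where the test's direction was up for all but the stromal list.

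In PC organoids, flagellin raised single genes such as Nos2, Duoxa2, Duox2 and Nox1, and genes of the chemokine and NF-kB lists. Nos2 rose from 1.07 ± 0.61 CPM (SD, n = 6) to 25.7 ± 12.6 CPM, a log2 fold change of 4.65 ± 0.41 (edgeR adjusted p = 2.6e-05), in every stimulated library. Duoxa2 rose by 4.11 ± 0.30, Duox2 by 3.42 ± 0.32 and Nox1, a superoxide-producing oxidase, by 2.81 ± 0.49. The neutrophil chemokine Cxcl2 rose by 4.38 ± 0.74, Ccl20 by 2.76 ± 0.30, Tnf by 2.85 ± 0.28 and Csf1, the macrophage growth factor, by 2.64 ± 0.18. Pigr, which carries immunoglobulin A across the epithelium, rose by 1.14 ± 0.11. The pore-forming Gsdmd rose by 0.74 ± 0.07 and Casp4, a caspase that senses lipopolysaccharide in the cytosol, by 1.26 ± 0.18. Tlr5 had a log2 fold change of -0.46 ± 0.22 (edgeR adjusted p = 0.62). Of 16325 genes, 91 rose and 20 fell. Of these, 34 rose and 0 fell at least 2-fold. The named falls were small: Selenbp1 fell by 0.80 on the log2 scale, Gvin1 by 0.73, Shank2 by 0.63, Aldh1l1 by 0.57 and the inflammasome receptor Nlrp6 by 0.55, with standard errors of 0.11 to 0.15. Limma on TPM called no fall, and with the length offset Selenbp1, Shank2, Aldh1l1 and Nlrp6 were not called. Of the named rises, Ceacam12 (3.02 ± 0.45) was called whichever library was left out, while Gbp6 (2.49 ± 0.45), a guanylate-binding protein, was not.

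Of 28 NF-kB pathway members and feedback regulators, 12 rose, 0 fell and 16 did not pass, and 16 rose when adjusted over the list alone. Tnfaip3 rose by 1.63 ± 0.13, Birc3 by 1.56 ± 0.13, Nfkbia, the inhibitor that NF-kB itself induces, by 1.47 ± 0.12 and Nfkb2 by 0.99 ± 0.09 (camera adjusted p = 5.0e-31, and 0.0019 with an estimated correlation). Of 10 chemokines 5 rose (8 over the list alone), among them Ccl28 by 0.86 ± 0.11 and Cxcl5 by 4.45 ± 0.80. Among those that did not pass, Ccl25 had a value of -0.10 ± 0.08 (camera adjusted p = 2.8e-17, and 0.0019 with an estimated correlation). Of 19 defence genes 7 rose (9 over the list alone), with Muc13 at 0.18 ± 0.08 among those that did not (camera adjusted p = 7.9e-20, and 0.0019 with an estimated correlation). Of 14 cytokines 3 rose, Tnf, Csf1 and Lif (0.75 ± 0.14), also over the list alone (camera adjusted p = 8.1e-05, and 0.011 with an estimated correlation). No single gene of 26 interferon-stimulated genes or 18 endoplasmic reticulum stress genes passed over all genes, but both lists lay higher together, with medians of 0.21 and 0.19. Their camera adjusted p was 0.00016 and 1.9e-10 (adjusted p = 0.0059 and 0.023 with an estimated correlation), and over the list alone 0 and 5 rose.

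Tlr2, a receptor for bacterial lipoproteins, rose by 1.23 ± 0.26 as 1 of 20 Toll-like receptor genes (3 over the list alone; camera adjusted p = 0.0050, adjusted p = 0.075 with an estimated correlation). Of 22 immediate early genes 1 rose, Maff by 0.56 ± 0.11 (2 over the list alone; camera adjusted p = 0.0012, adjusted p = 0.26 with an estimated correlation). Enterocyte markers lay lower with a median of -0.41 and none past the test (camera adjusted p = 1.2e-07, adjusted p = 0.19 with an estimated correlation). Colonocyte markers (median -0.29; camera adjusted p = 0.033, adjusted p = 0.084 with an estimated correlation) and cell cycle genes (median -0.13; camera adjusted p = 0.012, adjusted p = 0.60 with an estimated correlation) had no member past the test either. Of 15 stem cell markers Olfm4 rose by 1.53 ± 0.30 and Smoc2 fell by 0.26 (1 rose and 3 fell over the list alone, median -0.04, mean 0.06; camera adjusted p = 0.21). Cd44 rose by 0.42 ± 0.07 as 1 of 15 Wnt targets (1 rose and 2 fell over the list alone; camera adjusted p = 0.074), Ccl9 by 0.80 ± 0.15 as 1 of 14 goblet markers (camera adjusted p = 0.68) and Pecam1 by 0.71 ± 0.14 as 1 of 9 stromal and endothelial genes (camera adjusted p = 0.27). Of 11 genes of the sensor list, the inflammasome genes Gsdmd and Casp4 rose, and no Tlr5, Naip or Nlrc4 gene passed. Over the list alone 3 rose and 2 fell (median -0.03, mean 0.11, camera adjusted p = 0.53). No member passed over all genes among 22 Paneth markers (1 lower over the list alone; camera adjusted p = 0.64), 18 enteroendocrine markers (0.80), 11 tuft markers (0.64), 8 haematopoietic markers (0.19) or 7 mitochondrial transcripts (0.64, median 0.01, mean -0.09). Paneth lysozyme and defensin transcripts share reads between near-identical copies, so single members are uncertain. The fry test asks whether a list's genes move, on balance, one way, and its mixed form whether they change in either direction. Neither compares the list with other genes. Its adjusted p was 2.3e-05 for NF-kB, chemokine and defence lists, and its mixed adjusted p was 3.0e-08 for the sensors.

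Within the PC libraries without Y-linked transcripts (4 against 3) 21 genes were called, 20 of them among the 111, and within those with them (2 against 3) 26, 22 of them among the 111. All 91 rises and 20 falls had the same direction in both classes. Medians were 0.71 and 0.88 for the rises (0.76 in all libraries) and -0.36 and -0.52 for the falls (-0.45 in all). The genes were picked by their change over these same libraries, so their shared direction was largely set by that choice. Nos2 rose by 4.49 ± 0.32 without and 4.30 ± 0.30 with Y-linked transcripts, Duox2 by 2.66 ± 0.15 and 3.79 ± 0.31, Tnfaip3 by 1.40 ± 0.09 and 2.03 ± 0.20, Nfkbia by 1.23 ± 0.13 and 1.84 ± 0.12 and Tnf by 2.53 ± 0.33 and 3.17 ± 0.39. Ccl20 had values of 2.21 ± 0.36 (edgeR adjusted p = 0.076) and 3.34 ± 0.35 (0.012), and none of the 5 named falls passed in either class. With the class as a covariate 126 genes were called, 100 of them among the 111, and the calls of Tlr2 and Smoc2 ended. Cxcl2, Ceacam12, Nox1, Ccl28 and Cd44 were called in neither class alone, nor were Gbp6, Cxcl5, Lif and Maff. The share of rises among calls was 82.0%, against 100% of 37 calls in limma on TPM, 95.9% of 49 with the length offset and 63.3% of 332 with a replicate block. Leaving out PC unstimulated 1 or 2 left 66 or 70 calls, and leaving out flagellin 1, 5 or 6 left 61, 64 or 64. Of 32 named genes called, 19 passed whichever library was left out. The other 13 lost their call with at least 3 of the 12 libraries left out in turn, with highest adjusted p-values of 0.058 for Cxcl5, 0.056 for Gbp6, 0.073 for Selenbp1, 0.13 for Shank2, 0.067 for Aldh1l1, 0.11 for Nlrp6, 0.12 for Tlr2, 0.078 for Lif, 0.088 for Olfm4, 0.14 for Smoc2, 0.071 for Ccl9, 0.096 for Maff and 0.11 for Pecam1 in edgeR's test. Tlr2, Lif, Olfm4, Smoc2, Cd44, Ccl9, Maff and Pecam1 were called neither in limma on TPM nor with the length offset. Gbp6 was not called in limma on TPM, Cxcl5 in DESeq2, Nlrp6 and Smoc2 without a filter, or Gvin1, Olfm4, Smoc2 and Pecam1 with all libraries in 1 fit.

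In colon organoids, 27 genes of 15344 rose and none fell, 18 of them at least 2-fold. Ccl20, the ligand that draws Ccr6-bearing lymphocytes, rose from 0.145 ± 0.089 CPM (SD, n = 4) to 10.5 ± 3.1 CPM, a log2 fold change of 6.12 ± 0.35 (edgeR adjusted p = 2.4e-05). Duox2 rose from 48.0 ± 6.9 to 266 ± 28.2 CPM (2.47 ± 0.12; edgeR adjusted p = 8.8e-06), Duoxa2 by 2.83 ± 0.26, Duoxa1 by 2.67 ± 0.33, Nos2 by 2.89 ± 0.19 and Nox1 by 1.46 ± 0.17. Cxcl2 rose by 3.27 ± 0.46, Csf1 by 2.77 ± 0.31, Cxcl1 by 1.62 ± 0.24, the complement gene C3 by 1.57 ± 0.26, Tnf by 1.29 ± 0.14 and the keratin Krt36 by 2.09 ± 0.32. Tlr5 had a log2 fold change of -0.19 ± 0.26. At an unadjusted p under 0.05 there were 588 genes.

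Of 29 NF-kB genes 5 rose and 24 did not pass, and 17 rose when adjusted over the list alone. Zc3h12a, a nuclease that degrades cytokine messengers, rose by 1.20 ± 0.10, Birc3 by 0.78 ± 0.08, Tnfaip3 by 0.71 ± 0.09 and the kinase Ikbke by 0.69 ± 0.08 (camera adjusted p = 5.8e-28, and 0.0030 with an estimated correlation). Of 13 chemokines 4 rose (7 over the list alone), including Cxcl9 by 1.41 ± 0.23, while Ccl28 had a value of 0.58 ± 0.18 (camera adjusted p = 2.2e-15, and 0.0030 with an estimated correlation). Of 20 defence genes 8 rose (11 over the list alone), with Pigr at 0.33 ± 0.14 among those that did not (camera adjusted p = 8.4e-33, and 0.0070 with an estimated correlation). Of 14 cytokines 2 rose (3 over the list alone; camera adjusted p = 1.1e-06, and 0.0078 with an estimated correlation). In the remaining lists no member passed over all genes. Camera placed 12 Paneth markers (adjusted p = 0.038; 1 higher over the list alone), 14 goblet markers (0.015) and 18 endoplasmic reticulum stress genes (0.0013) higher, and 18 enterocyte markers (0.0055) and 7 mitochondrial transcripts (0.014; median -0.13) lower. Each of these calls was lost: adjusted p = 0.56 with an estimated correlation for the first 4 and 0.54 for the mitochondrial list. The other lists did not pass: Toll-like receptors (camera adjusted p = 0.26; 2 higher over the list alone), sensors (0.60; 1 higher), stem cells (0.39; 1 higher), Wnt targets (0.14), enteroendocrine (0.39), tuft (0.40), colonocyte (0.97), interferon (0.83), immediate early (0.60), cell cycle (0.94), haematopoietic (0.60) and stromal genes (0.66). Median and mean differed in sign for sensors (-0.02 and 0.04) and stromal genes (-0.02 and 0.03), both with test direction up.

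With the colon replicate number as a block, 68 genes were called in place of 27, with all 27 among them (65 rose and 3 fell), and no list call changed. DESeq2 called 64, the length offset 14 and 1 fit over all 26 libraries 17. Leaving out colon unstimulated 1, 2, 3 or 4 left 15, 15, 13 or 15 calls, and leaving out flagellin 1, 2 or 3 left 12, 12 or 15. Ccl20, Nos2, Duoxa2, Csf1, Duox2 and Zc3h12a passed in every alternative set beforehand. Duoxa1, Birc3, Ikbke, Tnf and Nox1 passed whichever library was left out, but Duoxa1, Tnf and Nox1 were not called with all libraries in 1 fit, Birc3 with the length offset, or Ikbke with that offset or in limma on TPM. Cxcl2, Cxcl1, Krt36, C3 and Cxcl9 were not called with all libraries in 1 fit either. The last 3 were also not called in limma on TPM or with the length offset, nor was Tnfaip3 with the offset. The highest adjusted p with a library left out was 0.12 for Cxcl2, 0.15 for Krt36, 0.14 for Cxcl1, 0.18 for C3, 0.10 for Tnfaip3 and 0.18 for Cxcl9 in edgeR's test. Tnfaip3 was lost without unstimulated 2 or 4 or flagellin 1 or 2, Cxcl9 without any 1 of the 8 libraries, and the other 4 without 6 or 7 of the 8.

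The responses of PC and colon organoids shared 15 raised genes: Birc3, Ccl20, Csf1, Cxcl2, Duox2, Duoxa2, Ikbke, Nfkb2, Nos2, Nox1, Noxo1, Tnf, Tnfaip3, Zc3h12a and 1 predicted gene. Of 14486 genes tested in both, 89 were called higher in PC and 24 in colon organoids, so independent lists would share 0.147 (one-sided Fisher's exact test, p = 2.4e-28; genes are not independent replicates). No gene fell in both, with 20 falls in PC and 0 in colon organoids. Log2 fold changes in PC and colon were 0.99 and 0.75 for Nfkb2, 0.86 and 0.65 for Noxo1, which organises the Nox1 complex, and 1.10 and 1.20 for Zc3h12a. SI shared 0 called genes with either type because edgeR called none there. Of the 84 genes raised in PC and tested in SI, 57 had positive SI values with a median of 0.10, and of 19 raised in colon, 17 were positive in SI with a median of 0.33. DESeq2 and the fit with a block gave 35 and 39 shared genes for PC and colon.

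**Figure D2:**
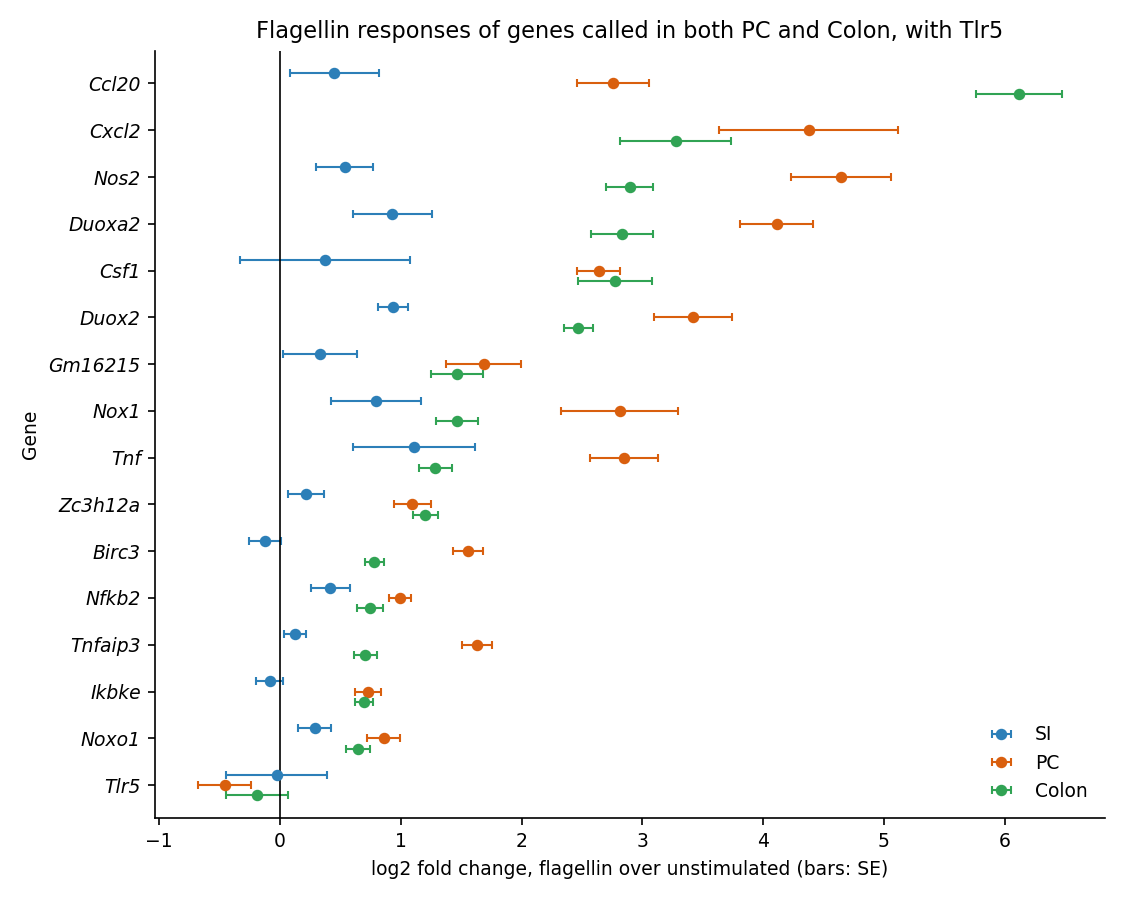
Log2 fold change after flagellin with its standard error for the 15 genes raised in both PC and colon organoids and for Tlr5, in SI (3 against 3 libraries, blue), PC (6 against 6, orange) and colon organoids (4 against 4, green). Cxcl2 was not tested in SI, and Ccl20 reached 6.12 in colon, 2.76 in PC and 0.45 in SI organoids.

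The difference of responses between PC and SI organoids asks which genes flagellin moved more in 1 type than in the other. Birc3 (1.67 ± 0.22), Tnfaip3 (1.5 ± 0.20), Nfkbia (1.29 ± 0.20) and Relb (1.23 ± 0.20) of the NF-kB list responded more in PC organoids, as did Nos2 (4.10 ± 0.60), Duoxa2 (3.17 ± 0.47), Clca3a2 (1.65 ± 0.24), a relative of calcium-activated chloride channel regulators, Pigr (1.01 ± 0.17) and Gsdmd (0.86 ± 0.15), all with 18 libraries. These 9 were the genes past the threshold of 18080 tested, and none responded less. Their edgeR adjusted p-values ran from 0.0037 to 0.036. Duox2 did not pass (2.48 ± 0.48; edgeR adjusted p = 0.11), nor did Tlr5 (-0.44 ± 0.38). Against the PC libraries with Y-linked transcripts alone, 13 genes were called, 7 of the 9 among them. Leaving out SI unstimulated 1, SI unstimulated 2 or SI flagellin 3 left 5, 5 or 3 calls. Birc3 alone passed in every alternative set beforehand. Tnfaip3, Relb and Gsdmd were not called in limma on TPM or with the length offset, Pigr with that offset, Clca3a2 in limma on TPM, or Gsdmd with DESeq2's size factors. Nos2 (adjusted p up to 0.062) and Duoxa2 (up to 0.060) were lost without SI flagellin 3. The highest adjusted p with a library left out was 0.12 for Nfkbia (lost without SI unstimulated 1 or 2 or flagellin 1 or 3), 0.17 for Relb (without SI unstimulated 1 or 2 or flagellin 2 or 3), 0.19 for Pigr (without 12 of 18) and 0.24 for Gsdmd (without 14 of 18) in edgeR's test. All 9 were higher, against 87.5% of 8 calls in limma on TPM, and DESeq2 called 35, 29 of them higher.

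Of 29 NF-kB genes 4 responded more in PC organoids (11 over the list alone; camera adjusted p = 6.5e-21, and 0.0038 with an estimated correlation). Defence genes (3 of 24, and 6 over the list alone) and chemokines (0 of 14, and 3 over the list alone) also lay higher, both with a camera adjusted p of 9.4e-10, and 0.0071 with an estimated correlation. Calls of other lists were lost with an estimated correlation. These were cytokines (0 of 17, 3 over the list alone; camera adjusted p = 0.017, adjusted p = 0.063 with an estimated correlation), interferon-stimulated genes (0 of 27, 1 over the list alone; 0.013, adjusted p = 0.10 with an estimated correlation) and endoplasmic reticulum stress (8.6e-05, adjusted p = 0.19 with an estimated correlation), all higher. Enterocyte markers (camera adjusted p = 1.5e-05, adjusted p = 0.35 with an estimated correlation), cell cycle genes (0.014, adjusted p = 0.58 with an estimated correlation) and mitochondrial transcripts (0.0042, adjusted p = 0.35 with an estimated correlation; median -0.34) lay lower, with no member past the test. No call was made for sensors (1 of 11, Gsdmd, and 2 over the list alone; camera adjusted p = 0.34, median -0.06, mean 0.09), Toll-like receptors (0.14; 2 over the list alone), immediate early genes (0.071; 1 lower over the list alone), Paneth (0.34), stem (0.062), goblet (0.25), enteroendocrine (0.46), tuft (0.71, median -0.06, mean 0.26), colonocyte (0.062), haematopoietic (0.14) and stromal markers (0.46, median 0.07, mean -0.14) or Wnt targets (0.52, median -0.07, mean 0.45).

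Between colon and SI organoids, Ccl20 (5.66 ± 0.59), Duox2 (1.51 ± 0.16) and Nos2 (2.33 ± 0.30) responded more in colon organoids, with edgeR adjusted p-values of 0.0010, 0.0010 and 0.0074 over 14 libraries. They were the genes past the threshold of 17002, and they passed in every alternative set beforehand. Unstimulated Ccl20 was near the floor in colon (0.145 CPM, against 3.71 CPM in SI), and its mean rose by 10.4 CPM in colon and 1.37 CPM in SI. Ikbke (0.76 ± 0.13; edgeR adjusted p = 0.058), Zc3h12a (0.97 ± 0.17; 0.065) and Birc3 (0.88 ± 0.15; 0.072) did not pass, nor did Ceacam2 (2.81 ± 0.53; 0.15) or Tlr5 (-0.18 ± 0.41). DESeq2 called 28 genes, the fit without a filter 10, the fit with a block 12 (11 of them higher) and limma on TPM 7, with 85.7% higher against 100% in edgeR. Leaving out SI unstimulated 1, SI unstimulated 3 or SI flagellin 2 gave 5 calls each, and leaving out colon flagellin 3 gave 7.

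NF-kB genes lay higher in the colon response than in the SI response (0 of 29 past the test, 5 over the list alone; camera adjusted p = 2.3e-10, and 0.0019 with an estimated correlation). So did chemokines (1 of 13, 2 over the list alone; 1.7e-07, and 0.0019 with an estimated correlation) and defence genes (2 of 23, 4 over the list alone; 6.2e-10, and 0.037 with an estimated correlation). The 7 mitochondrial transcripts lay lower with a median of -0.51, 6 of them over the list alone (camera adjusted p = 1.3e-07, and 0.045 with an estimated correlation). Mitochondrial genes took 2.3% to 2.53% of counts in unstimulated SI libraries and 2.72% to 3.75% in stimulated ones, which were also deeper. In colon libraries they took 2.89% to 3.43% and 2.6% to 2.83%. Whether depth or RNA quality had a part was not tested. In the other 17 lists no member passed over all genes, and the lowest camera adjusted p was 0.15. Over the list alone 2 cytokines and 1 Toll-like receptor gene were higher. Median and mean differed in sign for sensors (-0.03 and 0.01), Toll-like receptors (-0.03 and 0.06), enteroendocrine (-0.16 and 0.07), colonocyte (-0.06 and 0.27) and stromal genes (0.04 and -0.23).

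Between colon and PC organoids no gene of 17893 passed in edgeR's test, with 685 at an unadjusted p under 0.05. The smallest p-values were those of Ccl20 (3.38 ± 0.54, the larger response in colon; edgeR adjusted p = 0.059) and Steap4 (-3.46 ± 0.60; 0.10), Relb (-0.92 ± 0.17; 0.14), Tnfaip3 (-0.92 ± 0.18; 0.21) and Pigr (-0.81 ± 0.17; 0.34), with the larger values in PC. Ceacam12, Trpv3, Birc3 and Tnf followed with adjusted p-values of 0.35, 0.35, 0.44 and 0.51, and Tlr5 had a value of 0.27 ± 0.36. The Ccl20 value starts from a low colon base, 0.145 CPM against 1.18 CPM in PC, with rises of 10.4 and 6.82 CPM. DESeq2 called 19 genes and the fit with a block 13, with Ccl20, Relb, Tnf, Pigr and Trpv3 in both. Limma on TPM called 0. Without pseudogenes and genes under 400 bases Ccl20 passed (edgeR adjusted p = 0.047), and against PC libraries without Y-linked transcripts 3 genes passed, Ccl20 among them. Leaving out PC unstimulated 2 or 6, PC flagellin 1, colon unstimulated 4 or colon flagellin 3 gave 1, 2, 1, 3 or 2 calls.

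Camera calls between the colon and PC responses were lost with an estimated correlation. NF-kB genes lay lower in colon (5 lower over the list alone; camera adjusted p = 2.0e-05, adjusted p = 0.36 with an estimated correlation), as did interferon-stimulated genes (0.0010, adjusted p = 0.41 with an estimated correlation) and chemokines (0.040, adjusted p = 0.41 with an estimated correlation; 1 higher and 1 lower over the list alone). Higher were Paneth markers (0.043, adjusted p = 0.64 with an estimated correlation), Wnt targets (0.027, adjusted p = 0.36 with an estimated correlation), goblet markers (0.032, adjusted p = 0.41 with an estimated correlation) and cell cycle genes (0.040, adjusted p = 0.72 with an estimated correlation). The other 14 lists had camera adjusted p-values of 0.053 or more, and over the list alone 1 defence gene was higher and 4 lower, 1 stem marker higher and 1 sensor and 1 cytokine lower. Median and mean differed in sign for sensors (0.04 and -0.07), enteroendocrine (-0.14 and 0.14) and colonocyte markers (0.25 and -0.04), and for haematopoietic markers (0.05 and 0.27) the test's direction was down.

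Without stimulation, PC organoids held far more Paneth, enteroendocrine and goblet transcripts than SI organoids and far fewer enterocyte and cell cycle transcripts (6 against 3 libraries). Tlr5 was higher, at 7.77 ± 2.51 CPM (SD, n = 6) against 1.09 ± 0.19 (n = 3), a log2 fold change of 2.83 ± 0.36 (edgeR adjusted p = 2.5e-05); in TPM the ratio was 6.43. All 22 Paneth markers were higher, with a median of 5.67. Mmp7, the protease that activates defensins, rose by 5.92 ± 0.19 and Habp2 by 5.16 ± 0.16. The defensins Defa22 and Defa21, which share reads with other copies, rose by 7.58 ± 0.16 and 7.68 ± 0.19 (camera adjusted p = 6.3e-16, adjusted p = 0.077 with an estimated correlation). All 21 enterocyte markers were lower, with a median of -3.69: the disaccharidases Sis and Mgam by -3.69 ± 0.12 and -3.46 ± 0.09 and the glucose transporter Slc5a1 by -4.22 ± 0.13 (camera adjusted p = 1.8e-11, adjusted p = 0.20 with an estimated correlation). Of 16975 genes, 4753 were higher and 5258 lower, 2914 and 2318 of them at least 2-fold.

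Of 18 enteroendocrine markers 17 were higher (18 over the list alone), including the transcription factors Neurod1 (5.02 ± 0.18) and Insm1 (4.31 ± 0.16) and the serotonin-synthesis enzyme Tph1 (3.85 ± 0.13), with Ghrl (0.83 ± 0.37) not past the test (camera adjusted p = 7.9e-12, adjusted p = 0.060 with an estimated correlation). Of 14 goblet markers 12 were higher and 1 lower, with Spdef, the secretory-lineage transcription factor, at 3.64 ± 0.14 and Zg16 at -0.61 ± 0.29 not past the test (camera adjusted p = 1.3e-06, adjusted p = 0.064 with an estimated correlation). Of 15 Wnt feedback targets 12 were higher and 2 lower. Nkd1 rose by 5.79 ± 0.22, Apcdd1 by 6.63 ± 0.35 and Sox9 by 1.88 ± 0.12. Wif1 was 576 times as abundant (95% interval 103 to 22771.7) on 1 SI count (camera adjusted p = 2.3e-05, adjusted p = 0.060 with an estimated correlation). Of 20 cell cycle genes 18 were lower and 1 higher, with a median of -2.34 and Ccnb1 at -2.75 ± 0.21, Kif11 at -2.95 ± 0.25 and Birc5 at -2.27 ± 0.17 (camera adjusted p = 1.3e-06, adjusted p = 0.46 with an estimated correlation). Endoplasmic reticulum stress genes were higher (15 of 18, 1 lower; 16 and 1 over the list alone), Herpud1 by 1.57 ± 0.11 (camera adjusted p = 5.0e-05, adjusted p = 0.26 with an estimated correlation). Interferon-stimulated genes were higher too (14 of 26, 2 lower), Irf7 by 1.51 ± 0.15 and Stat2 by 1.05 ± 0.12 (camera adjusted p = 0.0069, adjusted p = 0.20 with an estimated correlation). All 7 mitochondrial transcripts were lower, with a median of -1.5 (camera adjusted p = 0.0069, adjusted p = 0.46 with an estimated correlation).

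The inflammasome genes Pycard (-3.15 ± 0.12), Il18 (-3.29 ± 0.30), Naip1 (-2.98 ± 0.10) and Casp1 (-2.39 ± 0.15) were lower in PC than in SI organoids, among 2 higher and 6 lower of 11 sensors (camera adjusted p = 0.21), while Naip6 was level (0.00 ± 0.11). Of 21 Toll-like receptor genes 8 were higher and 6 lower (camera adjusted p = 0.55; median 0.22, and -0.02 in limma on TPM), including Irak3, a brake on that pathway, at 4.52 ± 0.18. NF-kB genes (8 higher and 7 lower of 28; 0.71; median 0.11, and -0.20 in limma on TPM), chemokines (3 and 4 of 7; 0.74, median -0.46, mean 0.49; Ccl25 -2.05 ± 0.10, Cxcl16 2.39 ± 0.19), cytokines (6 and 7 of 15; 0.99, median 0.46, mean -0.26) and defence genes (7 and 5 of 19; 0.90, median 0.68, mean -0.34; Reg3a -6.03 ± 0.24, Pigr -2.02 ± 0.08) moved both ways. So did stem markers (7 and 6 of 17, 8 and 6 over the list alone; 0.74, median 0.21, mean -0.03, and -0.28 in limma on TPM), with Olfm4 at -7.53 ± 0.33 and Msi1 at 2.40 ± 0.15. Immediate early genes (11 and 4 of 21, 12 and 4 over the list alone; 0.098), colonocyte (4 and 3 of 12, 5 and 3 over the list alone; 0.71), stromal (5 and 0 of 10; 0.11; Vim 2.97 ± 0.25) and haematopoietic markers (2 and 1 of 10; 0.74; Lyz2 5.38 ± 0.26) had no camera call. Of 12 tuft markers 2 passed over all genes and 0 over the list alone (0.74; median 0.34, and -0.06 in limma on TPM). The calls of Avil and Pou2f3 were lost without SI unstimulated 1 or 3 and 1 or 2 (adjusted p up to 0.062 and 0.079 in edgeR's test). Both ended in limma on TPM, and that of Pou2f3 with a block.

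The largest rises were of genes with no SI count: Wscd1 (at least 224-fold), Ttc8 (at least 193-fold), Lmx1b (at least 160.4-fold), Cntfr (at least 137-fold) and Bpifa2 (at least 339.5-fold), the last lost in DESeq2, in limma on TPM and without any 1 SI library (adjusted p up to 0.096 in edgeR's test). The largest falls were Apol10a (2 counts against 731, a ratio of 0.00106 with a 95% interval of 0.00013 to 0.0039), Dmbt1 (-8.82 ± 0.24), an epithelial scavenger protein, Cfhr2 (-8.62 ± 0.34), Slco2b1 (-7.68 ± 0.28) and Aqp8 (-7.66 ± 0.57). Of the calls, 47.5% were higher, against 29.7% in limma on TPM. The PC libraries with Y-linked transcripts (2) against SI (3, all with them) gave 9321 calls, 8639 of them among the 10011. The culture conditions and any batch of the PC organoids cannot be told apart from the type.

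Colon organoids without stimulation (4 libraries) carried colon-region genes and lacked enterocyte transcripts of the small intestine (3 libraries). Tlr5 was at 9.36 ± 2.09 CPM (SD, n = 4) against 1.09 ± 0.19 (n = 3), a log2 fold change of 3.06 ± 0.25 (edgeR adjusted p = 1.0e-06); in TPM the ratio was 8.06. Of 16 colonocyte and colon-region markers 15 were higher, with a median of 5.60: Car4 by 10.26 ± 0.28 and Cldn8 by 7.22 ± 0.33, with Scnn1b (0.71 ± 0.43) not past the test (camera adjusted p = 7.2e-08, adjusted p = 0.17 with an estimated correlation). Of 21 enterocyte markers 20 were lower and 1 higher, with a median of -5.82: the lipid-transport gene Mttp by -7.72 ± 0.12, Apoa1 by -10.48 ± 0.21 and the peptidase Anpep by -6.99 ± 0.16 (camera adjusted p = 1.1e-08, adjusted p = 0.31 with an estimated correlation). Of 15947 genes, 5627 were higher and 5856 lower, 3412 and 2569 of them at least 2-fold. The largest rises were the carbonic anhydrase Car1 (at least 115805-fold), Ly6g (at least 6938-fold), Saa1 (at least 4699-fold), Hoxb13 (at least 3660.0-fold) and Atp12a (84115 counts against 2, a ratio of 34370.0 with a 95% interval of 9514 to 283809).

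The effective length lay further under the length in colon libraries than in SI libraries. Genes with at least 100 counts over all SI libraries were checked for counts in all colon libraries, stimulated or not. Of those of at most 200 bases, 37 of 37 had no colon count. Of the 92 over 250 bases but no longer than the bases taken off, 64 had none. Missing counts were not limited to those lengths: of 176 genes over 400 and up to 500 bases, 22 had no colon count and 0 had none in PC. The largest falls in assigned counts were Hist2h2aa2 (at least 8382-fold), mt-Atp8 (at least 6837-fold), Rps12 (at least 4834-fold), Reg3a (at least 2452-fold) and Gip (at least 2374-fold). Each had 0 counts in unstimulated colon libraries. Such a 0 may come from the quantification, so these bounds hold for the counts and were not read as bounds on expression. Of 22 Paneth markers 18 were lower and 3 higher, with a median of -7.91 (-5.79 with members at their bounds); Itln1 had a value of -9.85 ± 0.32, Mmp7 of -5.63 ± 0.19 and Ang4 of -0.36 ± 0.19 (camera adjusted p = 6.5e-05, adjusted p = 0.39 with an estimated correlation). Over the 7 Paneth markers of at least 1000 bases 6 were lower and 1 higher, with a median of -3.45. Among genes of that length 14 of 15 colonocyte markers were higher and 16 of 17 enterocyte markers lower. Of 857 genes that differed at least 32-fold, 310 (36.2%) were pseudogenes or genes under 400 bases, 279 of them lower, against 5.57% of other genes (two-sided Fisher's exact test, odds ratio 9.61, p = 1.1e-144).

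Immediate early genes were higher in colon organoids (18 of 21, 1 lower), Klf4 by 4.35 ± 0.16 and Atf3 by 2.41 ± 0.17 (camera adjusted p = 3.3e-05, adjusted p = 0.39 with an estimated correlation). Tuft markers were lower (10 of 11, median -2.62), Dclk1 by -2.62 ± 0.31 and the channel Trpm5 by -2.66 ± 0.31 (0.0041, adjusted p = 0.39 with an estimated correlation). So were cell cycle genes (18 of 20, 1 higher; median -0.66; 0.00010, adjusted p = 0.39 with an estimated correlation). Defence genes were higher too (16 of 21, 3 lower), Plaur by 3.90 ± 0.15 and the peptidoglycan-binding Pglyrp1 by 2.70 ± 0.15 (0.0027, adjusted p = 0.39 with an estimated correlation). So were chemokines (10 of 12, 2 lower; 0.031, adjusted p = 0.39 with an estimated correlation), with Cxcl16 at 2.68 ± 0.16 and, lower, Ccl25 at -3.28 ± 0.12 and Ccl20 at -4.63 ± 0.45. Interferon-stimulated genes were higher (16 of 24, 2 lower), Irf7 by 2.06 ± 0.17 (0.013, adjusted p = 0.54 with an estimated correlation). Toll-like receptor genes (11 of 20, 1 lower) and NF-kB genes (16 of 28, 6 lower) were at the threshold, each with a camera adjusted p of 0.0498 (adjusted p = 0.31 with an estimated correlation). Tlr4, the lipopolysaccharide receptor, was higher by 6.35 ± 0.34, Tlr1 by 3.15 ± 0.19 and Tnip3 by 5.98 ± 0.21.

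Lists without a camera call over all their members in this comparison held changed genes in both directions. Among 15 cytokines 9 were higher and 3 lower (camera adjusted p = 0.10), with the interleukin antagonist Il1rn at 7.41 ± 0.22 and Tnf at 4.14 ± 0.27. Among 14 goblet markers 8 were higher and 3 lower (0.061), with Zg16 at 4.46 ± 0.26 and Clca1 at 3.43 ± 0.23. Among 18 enteroendocrine markers 12 were higher and 5 lower (0.13), with the colonic peptide hormone Pyy at 8.76 ± 0.29. Over the 12 of them of at least 1000 bases, 10 were higher and 1 lower, with a call by camera's preset correlation (adjusted p = 0.012). Endoplasmic reticulum stress genes of that length also gained a call (2 higher and 12 lower of 17, camera adjusted p = 0.025). The other lists without a call gained none, and no estimated correlation was tried there. Stem markers (3 higher and 11 lower of 16; 0.061; Olfm4 -10.22 ± 0.67), Wnt targets (7 and 4 of 14; 0.55; median 0.32, and -0.06 in limma on TPM), endoplasmic reticulum stress (3 and 12 of 18; 0.061; Manf -1.10 ± 0.11), sensors (6 and 3 of 11; 0.48; camera up but fry down, fry adjusted p = 0.73; Pycard -2.35 ± 0.09, Gsdmd 1.19 ± 0.11), haematopoietic (1 and 3 of 7; 0.91, median 0.66, mean -0.16, test down) and stromal genes (4 and 1 of 7; 0.31) followed. Of 7 mitochondrial transcripts 1 was higher and 2 lower (1 and 1 over the list alone; 0.91, median 0.10, mean 0.05, test down): mt-Co1 at 1.10 ± 0.15, mt-Nd2 at -1.10 ± 0.09 and mt-Nd1 at -0.26 ± 0.10, which turned to 0.09 with the length offset. The call of mt-Nd1 also ended with DESeq2's size factors, without a filter, in limma on TPM, with a block and without SI unstimulated 2 or 3 or colon unstimulated 1, 2 or 4 (adjusted p up to 0.14 in edgeR's test). Of the calls, 49.0% were higher, against 37.1% in limma on TPM. All SI libraries held Y-linked transcripts and no colon library did, so that class and the type cannot be told apart.

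**Figure D3:**
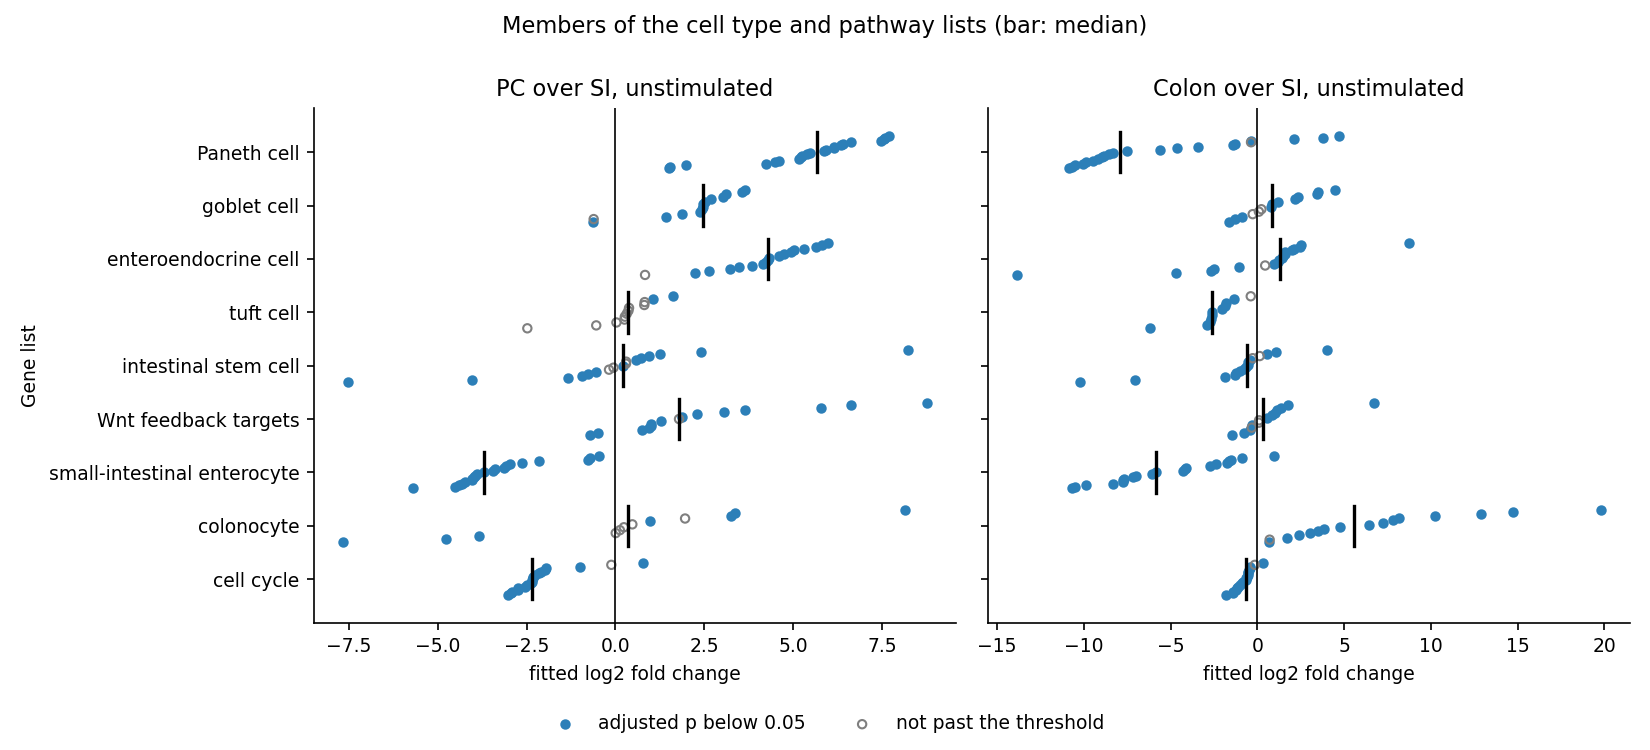
Fitted log2 fold change of each tested member of 9 gene lists in unstimulated PC against SI organoids (6 against 3 libraries) and colon against SI organoids (4 against 3), with adjusted p below 0.05 as filled points, others as open points and the list median as a bar. Paneth markers had medians of 5.67 in PC and -7.91 in colon organoids, and -3.45 in colon over the 7 of at least 1000 bases. Fitted values of genes without counts in a group depend on the prior count, and short genes often held no colon count.

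Tlr5 (ENSMUSG00000079164) lies on chromosome 1 at 182954788 to 182976044 on the forward strand, Duox2 (ENSMUSG00000068452) on chromosome 2 at 122279247 to 122298449 on the reverse strand and Nos2 (ENSMUSG00000020826) on chromosome 11 at 78920787 to 78960254 on the forward strand in GRCm38, where the annotation lists a protein-coding gene at each position.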

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

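The tests on sets of 3 against 3 libraries, SI limits, Tlr5 levels, gene length, Y-linked class and the other splits of the 3 flagellin responses were chosen after the results they bear on were seen; the split counts of the differences and baseline comparisons were set beforehand.

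A measure (total counts, 2 composition shares or the level of a gene) was tested within a group of 4 or more libraries 76 times, and 3 times a library lay far from the others, while chance gives about 1 in 20. PC flagellin 6 held 49822409 counts (49.8 mega-counts), where the next library held 31013635. In colon unstimulated 3 the 10 most abundant transcripts took 9.25% of counts, against 6.11% in the next. Nox1 stood at 416 CPM in colon flagellin 1, against 264 CPM in the next.

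Responses of PC and SI organoids differed by a test of the difference for Birc3 (1.67), Tnfaip3 (1.5), Nos2 (4.10), Duoxa2 (3.17), Clca3a2 (1.65), Nfkbia (1.29), Relb (1.23), Pigr (1.01) and Gsdmd (0.86), on the log2 scale. Responses of colon and SI organoids differed for Ccl20 (5.66), Duox2 (1.51) and Nos2 (2.33). Of 60 drawn splits of the PC and SI libraries, 1, the real one, gave as many as 9 genes, with 2 the highest of the others. The other splits mixed stimulated and unstimulated libraries within the types, which breaks up the flagellin effect itself. They therefore do not test whether the responses of the types were equal, and chance was not excluded for the difference. Of 60 drawn splits of the colon and SI libraries, 10 gave as many as 3 genes, so chance was not excluded. The highest of the others, 230, parted colon numbers 3 and 4 from 1 and 2, a structure of the samples. Among the 6 drawn splits that part as many pairs, the highest other count was 3. With a replicate block 12 genes were called. For colon against PC the real count was 0 (685 at an unadjusted p under 0.05 in edgeR, DESeq2 19, limma on TPM 0), so 60 of 60 drawn splits had to give at least as many and the count says nothing about chance; the highest gave 55.

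No SI gene passed edgeR's threshold (408 at an unadjusted p under 0.05; DESeq2 10, limma on TPM 0). Changes of the size seen in PC or colon could pass with as few libraries. Of 24 overlapping sets of 3 against 3 PC or colon libraries, 23 gave at least 1 call, from 0 to 45. These sets hold PC or colon changes, so they cannot tell whether smaller SI changes were missed for want of libraries. Duox2 in SI had a log2 fold change of 0.94 ± 0.12 (edgeR adjusted p = 0.11). A wider spread was argued against by 16 of 19 genes raised in colon organoids, whose upper 95% limit in SI lay below the PC change, though the other way round this held for 25 of 83. Whether lower Tlr5 in SI organoids had a part stays open, since Tlr5 level and type cannot be told apart: over 15 genes raised in PC and colon the median rise in CPM was 0.0958 of that in PC (Tlr5 ratio 0.140) and 0.0454 of that in colon (Tlr5 ratio 0.116), and single genes ran from -0.0796 (Ikbke) to 2.06 (Nox1) of the rise in PC, while other differences between the types are untested. The 6 SI libraries make 10 splits, too few for a share under 0.05; 10 of 10 gave at least the real 0, and the highest other gave 7.

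Large falls in colon against SI organoids gathered in short genes and pseudogenes. The fragment length set for the quantification is a candidate cause. Of genes no longer than the bases taken off, with at least 100 SI counts, 133 had no count in any colon library. Stimulated and unstimulated libraries were both counted, and 0 such genes had none in PC libraries. Not every such gene lacked colon counts: of the 92 over 250 bases, 64 had none. The fragment length was argued against for the colonocyte markers, since 14 of 15 with at least 1000 bases were higher. Of 35 splits of the unstimulated colon and SI libraries, 1 gave as many as 11483 genes and the highest other gave 0. For PC and SI this was 1 of 84, with 10011 and 0. Every other split mixed the types within a group, which widened its spread. These counts were therefore not read as excluding chance or a batch that goes with the type. Regional biology of Paneth cells and defensins stays open as untested.

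The PC response was weighed against the batch marked by Y-linked transcripts, which may be the sex of the animals. With that class as a covariate 100 of the 111 genes were called, which argues against the batch as the whole cause. Of 100 splits drawn from 462, 2 gave as many genes, the real one included. So high a count was rare among the drawn splits. The test was chosen after the response was seen and another grouping exceeded it, so chance was not excluded. The highest other, 253, grouped unstimulated 1 to 4 with flagellin 2 and 3 and followed the Y-linked class, where the fits within a class called 21 and 26 genes; the next gave 17. For the colon response 2 of 35 splits gave as many as 27 genes, so chance was not excluded by that count; the highest other, 376, set numbers 1 and 2 against 3 and 4, a structure of the samples, the highest other among the 8 splits that part every pair was 1, and the blocked count was 68.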

How the results depend on the processing

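The tests with the Y-linked class, within a class and without pseudogenes and genes under 400 bases were chosen after the data were seen. Of the results of named genes, 4227 kept their direction and side of the threshold. Of the others, 303 were no longer past it, 72 came past it and 6 reversed. List results covered camera calls under an estimated correlation, a replicate block and DESeq2's size factors. Of these, 142 kept direction and side, 47 were no longer past the threshold and 0 reversed. Nearly all of the losses came with the estimated correlation. Under it no list call held in the SI response, between the colon and PC responses or in either baseline comparison. Where counts of calls moved by over 1.5 times the cause was not tested. In SI they were 5 without a filter, 10 in DESeq2 and 1 with a replicate block. In PC they were 232 in DESeq2 (110 of the 111 among them), 37 in limma on TPM, 332 with the block, 49 with the length offset, 21 without and 26 with Y-linked transcripts. In colon they were 64 in DESeq2, 68 with the block, 14 with the length offset and 17 with all libraries in 1 fit. Between PC and SI they were 35 in DESeq2, 14 with the block and 5 with the length offset; between colon and SI 10 without a filter, 28 in DESeq2, 7 in limma on TPM and 12 with the block; between colon and PC 19 in DESeq2, 13 with the block, 3 against PC without Y-linked transcripts and 1 without pseudogenes and short genes. Shared genes were 1 for SI with PC and 1 for SI with colon, each without a filter and in DESeq2, and 35 (DESeq2) and 39 (block) for PC with colon.

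Leaving out each library gave 0 to 2 calls in SI, 61 to 116 in PC, 12 to 25 in colon, 3 to 10 between PC and SI, 3 to 7 between colon and SI, 0 to 3 between colon and PC, and 8852 to 9886 and 10757 to 11323 for unstimulated PC and colon against SI. Log2 fold changes of Tlr5 ran from -0.133 to 0.137 in SI, from -0.329 to 0.0108 in colon and from -0.324 to 0.0300 between colon and SI when each library was left out. They reversed in SI without unstimulated 3 (0.137) or flagellin 1 (0.00798), in colon without flagellin 1 (0.0108), between colon and SI without colon flagellin 1 (0.0300), and between colon and PC against PC without Y-linked transcripts (-0.0818). That of mt-Nd1 in colon against SI reversed with the length offset (0.0923). The cause was not tested. Same-numbered SI libraries had correlations of 0.084, 0.090 and 0.108, every one best with its own number. PC libraries had 0.061, 0.111, 0.212, 0.422, 0.306 and 0.189, not every one best with its own number. Both are a hint from the data and not the design. PC unstimulated 1 and PC flagellin 1 differ in Y-linked class, so PC counts with the block, and overlaps drawn from them, rest on an unlike pair. With the block the cytokine list between PC and SI had a camera adjusted p of 0.052 in place of 0.017; it changed no other list call. No list with a camera call changed the sign of its median between TMM, DESeq2's size factors, limma on TPM and the length offset. Lists without a call that did were stem, goblet, enterocyte, interferon, immediate early, endoplasmic reticulum stress, cell cycle and stromal genes in SI, mitochondrial transcripts in PC, and colonocyte, cell cycle and stromal genes in colon. Between PC and SI it was tuft markers, between colon and SI sensors, Toll-like receptors, stem, colonocyte, interferon, immediate early, cell cycle and stromal genes, and between colon and PC cytokines, defence and haematopoietic genes. In unstimulated organoids they were Toll-like receptors, NF-kB, stem and tuft genes for PC against SI and Wnt targets for colon against SI.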

Other observations

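The values below were chosen after the data were seen, and no further tests were run on them.

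Levels of some receptors for bacterial products lay apart between unstimulated organoid types and others lay closer (CPM, mean ± SD; 3 SI, 6 PC and 4 colon libraries). Tlr4, the lipopolysaccharide receptor, stood at 0.337 ± 0.35 in SI, 2.03 ± 0.87 in PC and 29.2 ± 1.26 in colon organoids, and its partner Cd14 at 6.75 ± 1.43, 2.60 ± 0.75 and 32.5 ± 3.3. Tlr1 stood at 5.26 ± 1.61, 0.805 ± 0.32 and 47.1 ± 5.66, and Tlr2 at 1.71 ± 0.43, 5.54 ± 1.77 and 7.32 ± 1.01. Tlr3, which binds double-stranded RNA, stood at 19.2 ± 2.4, 12.8 ± 1.7 and 18.7 ± 0.76. Of the cytosolic sensors, Naip1 stood at 258.9 ± 11, 32.8 ± 4.5 and 413 ± 33, and Naip6 at 449, 449 and 295. Naip2 stood at 127 ± 9.7, 138 ± 11 and 144 ± 1.5, and Naip5 at 93.4 ± 4.9, 131 ± 7.4 and 100.001 ± 5.9. Casp1 stood at 90.2 ± 4.9, 17.2 ± 3.9 and 108 ± 2.9, and Irak3 at 1.29 ± 0.31, 29.5 ± 2.7 and 2.52 ± 0.27. Naip copies share reads, so single members are uncertain. Tlr11 had no count in any of the 3 types.

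The most abundant genes also set the types apart. In unstimulated PC organoids Itln1, an intelectin, stood at 41810 ± 7993 CPM (944 in SI and 1.05 in colon organoids) and Lyz1 at 33610 ± 3754 (574 and 23.7), and the 10 most abundant transcripts took 17.5% to 21.0% of counts. In SI organoids Dmbt1 stood at 5387 ± 810 (12 in PC, 6770 in colon). In colon organoids Car1 stood at 4954 ± 1851 and was listed at 0 in both other types, and Ahnak at 7125 ± 726 (293 in SI and 129.9 in PC organoids). Lars2 stood at 35480.2 CPM in colon unstimulated 3 and at 2907 to 5163 in the other 3 libraries.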
